A study of Mus musculus with 14 samples.

How the data were processed

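The samples are 14 bulk RNA libraries from whole frozen tumours, extracted with Trizol and prepared with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited 1 table of expression signal per gene symbol for all tumours. The name of the table calls the values TPM, but the columns sum to between 879385 and 1084401 and 5 of 14 exceed the sum that TPM columns have, so the authors' signal is a TPM rescaled between samples in a way not given in the sources used here. The submitters' processing notes name kallisto, sleuth and the mm10 build, with no versions. Of 18481 genes listed, 0 are at 0 in all columns, so genes without signal were left out before deposit. In the table, 54 rows repeat the values of another row. Values at 0 can be failed estimates. Without counts the depth per sample is unknown. Strand use in counting is not given in the sources used here.

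Symbols were restored to their official case by matching to a mouse gene name table, which succeeded for 17810 symbols (96.4%). Coordinates come from GENCODE M21 on GRCm38, the same assembly as mm10. All 14 columns were used. A column's name gives its group but not which animal, so its number is only a name. The p-values measure the spread between these tumours. Before the data were examined it was planned to average the left and right tumours of each of the 2 day 27 mice. The columns do not allow this, so the 4 tumours entered as separate samples, and the 3 possible pairings were run as alternatives chosen after seeing the data. For the other groups the labels of days 3 and 6 carry different animal numbers within a group, but 1 number stands for both a control of day 6 and a PLX4032 tumour of day 3, and the labels do not say whether that is 1 animal. Those of day 18 say only that there are 2 samples, whose spread may be partly technical. No pair of columns was identical: the correlation of log2 values between tumours of a group ran from 0.962 to 0.99.

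Values were taken as log2(value + 1) for the 15841 genes that reached 1 in at least 2 tumours. The filter and test were set for TPM and kept for this signal. limma 3.58.1 in R 4.3.3 was fitted to the means of 6 groups with a variance trend (8 residual degrees of freedom), 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each treated day was compared with the mean of both control groups, days 18 and 27 with days 3 and 6, and control day 6 with control day 3. Where a group of 2 is reduced to a lone tumour, that tumour is assumed to vary like the other groups.

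Gene lists of pathways and cell types were written before the data were examined: 34 lists, of which 33 had the minimum of 4 tested genes, while the Y-linked list had 3. Of 542 list genes tested, 14 belong to more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with limma's fry, which tests whether the genes of a set move on balance without comparing them with other genes. Over the 6 comparisons camera called 92 results with the preset correlation and 0 with the estimated one. Of the lists that camera called with the preset correlation, fry also called 20 of 21 at day 3, 8 of 15 at day 6 and 10 of 20 at day 18. It called 0 of 7 at day 27, 14 of 17 late against early and 0 of 12 between the controls. Named genes follow a rule set at the same time: per comparison the 8 largest rises and 8 largest falls among called genes without overlap between the sides and with a mean of 5 or more on the higher side, leaving out predicted genes, pseudogenes and clone names; up to 4 members with the smallest p of each list described; and 16 genes fixed in advance. Some genes that this rule names are not reported here.

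The steps were tested on simulated log2 values for the 15841 genes, built from the real means and residual SDs, with 200 genes changed per comparison by 1, 2 or 3 log2 units. The 200 genes were drawn only from those with higher means. The genes of 1 list (G2/M) and of chromosome 6 were also shifted, and count among the changed genes below. Every value was drawn independently, so the simulation holds no correlation between genes and no tumours that share a mouse. The shares below can therefore overstate what the real tumours allow. Of genes changed by 1 log2 unit, 79.1% were recovered for day 3, 85.1% for day 6, 82.1% for day 18, 80.6% for day 27, 85.1% for late against early and 67.2% for control day 6 against control day 3. Of genes changed by 2 units the shares were 95.5%, 94.0%, 95.5%, 95.5%, 98.5% and 88.1%. Unchanged genes called numbered 18 of 284, 13 of 280, 16 of 258, 20 of 326, 16 of 367 and 15 of 223 calls.

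Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, filters at 5 and at any value above 0, median-of-ratios rescaling, quantile normalisation, no variance trend, sample weights, a fit on the compared groups alone, other uses of the controls, and leaving out each tumour. A mouse effect was planned as well, but the pairings it was run on were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.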

Results

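Gene expression was measured by RNA sequencing in 14 tumours grown from SMM102, a mouse melanoma cell line, under the skin of female C57BL/6J mice. Treatment began at a tumour volume of 150 to 300 mm3. Tumours under PLX4032 (vemurafenib, an inhibitor of the BRAF kinase, given into the peritoneal cavity at 50 mg/kg on 5 days per week) were taken on day 3 (n = 2), day 6 (n = 2), day 18 (n = 2) and day 27 (n = 4). Control tumours were taken on day 3 (n = 2) and day 6 (n = 2). The sample labels call the controls untreated, while the series' design text gives them the vehicle. The 4 tumours of day 27 came from 2 mice, a left and a right tumour of each. The table does not tie its columns to mice, so they were tested as 4 samples and every p-value that includes day 27 is too small. All comparisons share 1 estimate of the spread, to which these 4 tumours give 3 of the 8 residual degrees of freedom, so the p-values of the other days rest on it as well. The columns carry numbers that only name the tumours within a group.

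The deposited values lie on a per-million scale, with column totals from 879385 to 1084401. Read depth cannot be recovered from them, so no counting error is given. Of 18481 genes listed, 15841 reached a value of 1 in at least 2 tumours and were tested. Changes are differences of log2(value + 1) from limma with their standard error (SE), and calls use a Benjamini-Hochberg adjusted p under 0.05. The change understates the fold of genes with low values. Levels are means ± SD of the deposited values.

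Of 22 genes of melanocyte differentiation on the list, 11 reached the level for testing in at least 2 of the 14 tumours. In the controls Met, which is also on that list, averaged 21.3 ± 4.1 (SD, n = 4). Mitf, the master regulator of the melanocyte lineage, averaged 3.56 ± 0.90 (SD, n = 4), and Sox10, a neural crest transcription factor, averaged 0.0756 ± 0.068 (SD, n = 4). Mlana and Dct are absent from the table, as are 8 other genes of the list. Vim, an intermediate filament of mesenchymal cells, averaged 5810 ± 820 (SD, n = 4) and Axl, a receptor tyrosine kinase, 395 ± 38 (SD, n = 4).

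The first comparison asked what the tumours expressed after 3 days of BRAF inhibition. Genes of cell division fell and genes of the immune system rose. Mki67, a marker of cycling cells, went from 51.6 ± 6.9 (SD, n = 4) in the controls to 15.0 ± 1.0 (SD, n = 2), a log2 change of -1.71 (SE 0.12, adjusted p = 9.8e-06). Cd274, which encodes the checkpoint ligand PD-L1, went from 6.59 ± 2.4 (SD, n = 4) to 60.8 ± 12 (SD, n = 2), a log2 change of 3.07 (SE 0.47, adjusted p = 0.00062). In all, 7249 of the 15841 genes changed, 3947 higher and 3302 lower, and the higher ones were 54.4% of the calls.

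All 24 mitotic genes of the G2/M list fell, also 24 adjusted over the list alone, with a median log2 change of -1.87. The members with the smallest p were Cdc20, an activator of the anaphase-promoting complex (-2.44), the kinase gene Aurka (-2.09), the cyclin gene Ccnb1 (-2.35) and the kinesin gene Kif20a (-2.09). Of 24 genes of the G1/S list 23 fell, also 23 adjusted over the list alone, with a median of -1.30; among them were Tk1 (-1.41), Cdc45 (-1.62), Uhrf1 (-1.69) and Mcm5 (-1.49), which serve DNA replication and its upkeep. In limma's camera test against all other genes, with a preset correlation between genes, both lists were lower (adjusted p = 3.8e-21 for G2/M and 9.0e-16 for G1/S); with an estimated correlation both calls were lost (adjusted p = 0.453 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 20 cases, 18 adjusted over the list alone, with a median of -1.45. Fdft1 (-1.92) and Sqle (-2.38) were among those that fell (camera adjusted p = 2.0e-05; adjusted p = 0.466 with an estimated correlation). The list's mean in control day 6 tumour 1 was 1.48 log2 units under the mean of the controls, close to the 2 treated tumours, which lay 1.5 and 1.61 under it.

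Genes switched on by the MAPK pathway, the cascade that BRAF drives, were lower as a list. Of 21 tested, 13 fell and 1 rose, with the same numbers adjusted over the list alone, and the median was -0.71 (camera adjusted p = 0.00017; adjusted p = 0.453 with an estimated correlation). Etv4, an ETS transcription factor, fell from 95.0 ± 32 (SD, n = 4) to 17.4 ± 6.8 (SD, n = 2), and Ccnd1, which encodes cyclin D1, fell from 478 ± 120 (SD, n = 4) to 129 ± 0.87 (SD, n = 2). Their log2 changes were -2.38 (SE 0.24, adjusted p = 6.2e-05) and -1.84 (SE 0.18, adjusted p = 5.9e-05). Fosl1 (-2.08), Etv5 (-0.89), and the feedback inhibitor genes Spry4 (-0.87) and Dusp6 (-0.49, adjusted p = 0.029) also fell. The member that rose was Fos (3.19), an immediate early gene. Of 15 immediate early genes 7 rose and 1 fell, the same adjusted over the list alone, with Atf3 (3.20), Zfp36 (2.01) and Klf2 (1.56) among those that rose (camera adjusted p = 0.021; adjusted p = 0.466 with an estimated correlation).

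Markers of immune cells rose across several types. Of 20 T cell genes 19 rose (19 adjusted over the list alone, median 2.60), among them Foxp3 (2.06), Cd5 (2.84), Lck (2.95) and Cd28 (2.17). All 17 genes of cytotoxic lymphocytes and NK cells rose (17 adjusted over the list alone, median 2.76), with the smallest p for Ctsw (3.17), Xcl1 (3.04), Klrb1c (2.76) and Klrd1 (2.83). Cd8a, the co-receptor of cytotoxic T cells, went from 1.76 ± 0.38 (SD, n = 4) to 13.9 ± 2.5 (SD, n = 2). Of 22 genes of macrophages and monocytes 21 rose (22 adjusted over the list alone, median 2.64), including Cd68 (2.62), Folr2 (3.53), Tyrobp (2.65) and the chemokine receptor gene Ccr2 (3.32), while C1qa, a complement gene of macrophages, rose by 2.54. Of 15 dendritic cell genes 14 rose (14 adjusted over the list alone, median 1.67), with the smallest p for Batf3 (3.35). The camera adjusted p lay between 8.7e-08 and 1.2e-05 for these 4 lists, and each call was lost with an estimated correlation (adjusted p = 0.453 with an estimated correlation). Ptprc, the pan-leukocyte gene, stood at 120.5 and 182.8 in the 2 treated tumours against 6.01 to 29.2 in the controls.

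Interferon and antigen presentation genes rose with them. All 24 interferon response genes rose (24 adjusted over the list alone, median 2.42), with Irf1 (1.82), Gbp2 (2.90) and the chemokine gene Cxcl9 (3.78) among them. All 16 genes of MHC class I presentation (16 adjusted over the list alone, median 2.06) and all 12 of class II (12 adjusted over the list alone, median 2.87) rose, among them Tap2 (2.09), B2m (1.68), H2-T23 (2.95), Ifi30 (2.78) and Ciita (2.79), the class II transactivator. Classical and nonclassical H2 genes resemble each other, so reads can be shared between them and their single levels are uncertain. Of 16 checkpoint genes 14 rose, the same number adjusted over the list alone, including Pdcd1lg2 (2.91), Ctla4 (2.79) and Tnfrsf4 (2.32). Of 19 chemokine genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Ccl7 (3.01), Ccl8 (3.40), Ccl11 (2.96) and Ccl5 (3.76) rising. These 5 lists had camera adjusted p-values from 2.2e-07 to 8.1e-05; with an estimated correlation each call was lost (adjusted p = 0.453 with an estimated correlation, 0.462 for the interferon list). Of 16 complement and coagulation genes 12 rose and 1 fell, the same adjusted over the list alone, with C2 (2.35), C3 (4.74), C1ra (3.27) and C1s1 (3.32) rising (camera adjusted p = 0.00037; adjusted p = 0.453 with an estimated correlation).

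Part of the stromal markers rose. Of 18 endothelial genes 15 rose (16 adjusted over the list alone, median 0.97), with Tek (1.36) and Pecam1 (1.62) among them, and of 24 fibroblast and matrix genes 15 rose and 3 fell (16 and 3 adjusted over the list alone, median 0.52), with Dcn (1.23), Lum (1.24) and Col1a1 (0.99). Their camera adjusted p-values were 0.00063 and 0.0097; with an estimated correlation they were not called (adjusted p = 0.466 and adjusted p = 0.462 with an estimated correlation). Fat and muscle markers also stood higher in these tumours: 5 of 13 adipocyte genes rose, also 5 adjusted over the list alone, while of 18 skeletal muscle genes 1, Mb (2.30), rose and 0 did so adjusted over the list alone (camera adjusted p = 0.0059 and 0.012; adjusted p = 0.466 and adjusted p = 0.616 with an estimated correlation). Of 3 transcripts of the Y chromosome, which the female hosts lack, 1 fell, 0 adjusted over the list alone. Ddx3y went from 21.4 to a mean of 11.2 (log2 change -0.87, adjusted p = 0.04), while Kdm5d (-0.61, adjusted p = 0.20) and Uty (-0.46, adjusted p = 0.30) did not pass the test. Xist, expressed from the inactive X chromosome of female cells, stood at 51.3 and 78.5 in the treated tumours against 7.98 to 24.7 in the controls.

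The 8 largest rises at day 3 among genes whose tumours did not overlap between the sides were Retnla (5.31), Marco (5.28), Ly6i (5.24), the T cell receptor segment Trbj1-5 (5.09), Lyz1 (5.05), Saa3 (4.77), C3 (4.74) and Ly6c2 (4.68). Retnla, a marker of alternatively activated macrophages at chromosome 16 from 48842551 to 48844461 of the GRCm38 build, went from 0.499 ± 0.45 (SD, n = 4) to 56.9 ± 9.5 (SD, n = 2). Lyz1 and the Ly6 genes have close paralogs with which reads can be shared, so their levels are uncertain. Among the 8 largest falls were Nptx1 (-4.31), the incretin receptor gene Glp1r (-3.62), Atg9b (-3.20), Ngef (-2.87), the chloride channel gene Ano1 (-2.84), the chromatin protein gene Hmga1 (-2.83) and the cytokine gene Il11 (-2.72, adjusted p = 0.041). Hmga1 was abundant, going from 2470 ± 490 (SD, n = 4) to 341 ± 16 (SD, n = 2). Mitf rose by 1.04 and Axl fell by 0.37, while Egfr (0.75, adjusted p = 0.050) and Pdgfrb (-0.34, adjusted p = 0.11) were not called. Without treated tumour 2 the count was 4345 genes. Quantile normalisation shifted the median change of all genes from 0.02 to -0.15 and left 38.9% of the calls higher.

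**Figure D1:**
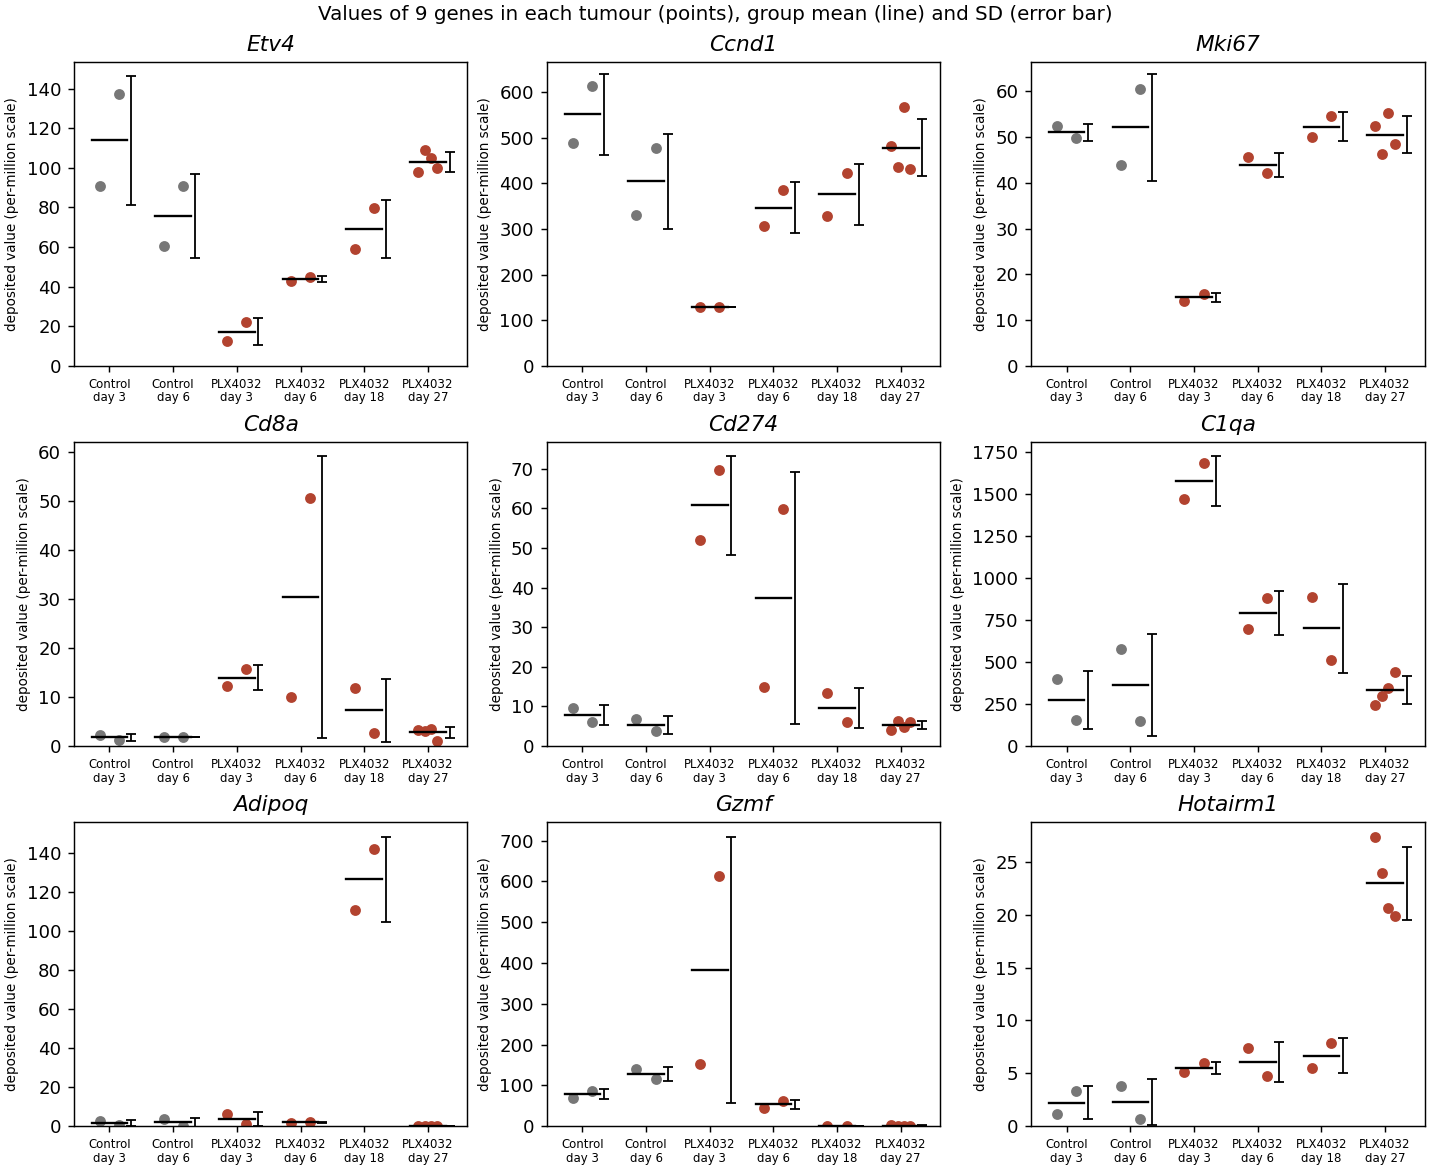
Deposited values (per-million scale, y axes from 0) of 9 genes in each tumour, by group on the x axes; points are tumours, lines are group means and error bars are SDs (n = 2, or 4 at day 27), with controls in grey and PLX4032 in red. Mki67 lay at 15.0 ± 1.0 at day 3 against 51.6 ± 6.9 in the 4 controls and at 43.9 ± 2.5 at day 6, and Gzmf, at 104 ± 32 in the controls, lay at 0.11 and 1.38 on average on days 18 and 27.

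At day 6 the immune genes stood high while the cell division genes were close to their control levels. Cd8a reached 30.3 ± 29 (SD, n = 2), a log2 change of 3.12 (SE 0.60, adjusted p = 0.034), and Cd274 reached 37.5 ± 32 (SD, n = 2), a log2 change of 2.10 (SE 0.47, adjusted p = 0.036). Mki67, at 43.9 ± 2.5 (SD, n = 2), had a log2 change of -0.22 (adjusted p = 0.33). In all, 937 genes changed, 711 higher and 226 lower, and 75.9% of the calls were higher. The 2 treated tumours differed in immune content: their T cell list means lay 1.21 and 2.64 log2 units over the controls, and Ptprc stood at 57.2 and 140.3.

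All 16 MHC class I genes rose (16 adjusted over the list alone, median 1.75), with the smallest p for Erap1 (1.07), H2-Q4 (2.01), Tap2 (1.70) and Tap1 (1.96). Of 24 interferon response genes 20 rose, 24 adjusted over the list alone, with a median of 2.51; Gbp3 (2.30), Zbp1 (2.82) and Irf9 (1.40) were among them. Of 20 T cell genes 15 rose (18 adjusted over the list alone, median 1.94), including Lck (2.37), Cd8b1 (2.94) and Cd3e (2.47), and of 17 cytotoxic and NK cell genes 9 rose (15 adjusted over the list alone, median 1.81), including Ctsw (2.5), Klrk1 (2.75) and Nkg7 (2.73). The camera adjusted p of these 4 lists lay between 3.5e-17 and 1.9e-10, and each call was lost with an estimated correlation (adjusted p = 0.343 with an estimated correlation). Fewer genes of myeloid cells passed over all genes: 3 of 22 macrophage genes rose, 12 adjusted over the list alone, and 3 of 15 dendritic cell genes, 10 adjusted over the list alone (camera adjusted p = 1.1e-07 and 2.4e-06; adjusted p = 0.488 and adjusted p = 0.343 with an estimated correlation). Of 16 checkpoint genes 8 rose, 12 adjusted over the list alone, with Pdcd1lg2 (1.49), Tigit (1.84), Havcr2 (1.88) and Lgals9 (2.22) (camera adjusted p = 5.3e-08; adjusted p = 0.343 with an estimated correlation).

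The MAPK list was lower in the camera test at day 6 (adjusted p = 0.00027; adjusted p = 0.343 with an estimated correlation), with a median of -0.40. Etv4, at 43.9 ± 1.7 (SD, n = 2), fell by 1.04 on the log2 scale (adjusted p = 0.036), and Fos rose by 2.19. Adjusted over the list alone 5 members fell and 1 rose, against 1 and 1 over all genes. Dusp6 (0.01, adjusted p = 0.97), Spry4 (-0.30, adjusted p = 0.37), Etv5 (-0.31, adjusted p = 0.24) and Ccnd1 (-0.44, adjusted p = 0.18) did not pass. Of 24 G2/M genes 0 were called over all genes or over the list alone, with a median of -0.13 (camera adjusted p = 0.0089; adjusted p = 0.871 with an estimated correlation), and 1 of 24 G1/S genes rose, also 1 over the list alone (median 0.13, camera adjusted p = 0.056). Y-linked genes had a median of -0.81 and 0 of 3 were called over all genes, 1 lower adjusted over the list alone.

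The 8 largest rises at day 6 were the monocyte genes Ly6c2 (4.22), Cd300e (4.13) and Ms4a4c (3.52) with Ly6i (3.79), the chemokine gene Ccl4 (3.71), Gpr31b (3.61), the B cell receptor modulator gene Cd72 (3.41) and Sirpb1a (3.36). Gpr31b went from 0.686 ± 0.30 (SD, n = 4) to 20 ± 7.7 (SD, n = 2). The 8 largest falls were Glp1r (-3.58), Nptx1 (-3.52), Ano1 (-3.24), the laminin gene Lama5 (-2.87), the bone matrix gene Dmp1 (-2.60), Sned1 (-2.54), Nrn1 (-2.52) and the prostaglandin receptor gene Ptgfr (-2.24). Pdgfrb fell by 0.72, and C1qa (1.54, adjusted p = 0.094), Egfr (0.73, adjusted p = 0.16), Mitf (-0.23, adjusted p = 0.69), Axl (0.01, adjusted p = 0.96) and Col1a1 (0.51, adjusted p = 0.24) were not called. The count rested on single libraries: it was 1 gene without treated tumour 2, 0 without control day 3 tumour 2, 26 without control day 6 tumour 2, 2145 without control day 6 tumour 1 and 8 against the day 6 controls alone, while a limma fit on the compared groups alone called 0 genes. In the fit of all groups 3584 genes had an unadjusted p under 0.05. Quantile normalisation left 60.4% of the calls higher.

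The day 18 tumours were compared with the same 4 controls of days 3 and 6, since no later control was taken. Treatment and time can therefore not be told apart at day 18 or day 27. The labels do not say whether the 2 tumours of day 18 came from 2 mice. Genes of fat cells had the largest median change of the 33 lists tested. Adipoq, the adipocyte hormone adiponectin, went from 1.78 ± 1.6 (SD, n = 4) to 127 ± 22 (SD, n = 2), a log2 change of 5.70 (SE 0.52, adjusted p = 0.00012), and Cfd, the adipocyte protease adipsin, went from 10.2 ± 12 (SD, n = 4) to 1610 ± 180 (SD, n = 2). In all, 1254 genes changed, 858 higher and 396 lower, and 68.4% of the calls were higher.

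All 13 adipocyte genes rose, also 13 adjusted over the list alone, with a median of 5.05 (camera adjusted p = 1.2e-21, adjusted p = 0.155 with an estimated correlation). The members with the smallest p were Pck1 (4.42), Plin1 (5.35), Lipe (2.69) and Fabp4 (5.08), which serve fat storage and its release. The list means lay 4.56 and 5.00 log2 units over the controls in the 2 tumours. Skeletal muscle genes split them: the list mean was 1.24 under the controls in tumour 1 and 2.93 over them in tumour 2, and 0 of 18 genes were called either way. Beside these, 8 of 24 fibroblast and matrix genes rose (13 rose and 1 fell adjusted over the list alone), with Lum (2.07), Fbln1 (2.87) and Col1a1 (1.33) (camera adjusted p = 0.019; adjusted p = 0.642 with an estimated correlation). Of 9 genes of Schwann cells and nerve 3 rose, among them Scn7a (2.21) and Mbp (1.60), 4 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.642 with an estimated correlation).

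Chemokine, complement and macrophage genes rose in part. Of 19 chemokine genes 8 rose and 1 fell (13 and 1 adjusted over the list alone), with Ccl11 (3.46), Cxcl14 (4.11) and Ccl7 (2.40) rising, and of 16 complement genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), with C3 (3.91), C4b (3.66) and Plau (1.35), the urokinase gene, rising. Of 22 macrophage genes 3 rose, Folr2 (2.77), Ly6c2 (3.11) and Cd163 (2.16), and 6 adjusted over the list alone. Of 20 T cell genes 0 were called over all genes or over the list alone, with a median of 0.97. The camera adjusted p was 8.6e-05 for chemokines, 0.00015 for complement, 0.00013 for macrophages and 0.00094 for T cells; with an estimated correlation each call was lost (adjusted p = 0.515, adjusted p = 0.515, adjusted p = 0.642 and adjusted p = 0.642 with an estimated correlation). Of 15 immediate early genes 6 rose, 11 adjusted over the list alone, with Fos (4.15), Cyr61 (1.46), Egr2 (2.22) and Zfp36 (1.74) (camera adjusted p = 1.5e-05; adjusted p = 0.515 with an estimated correlation).

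Cell division genes were at or slightly over control levels on day 18. Of 24 G1/S genes 4 rose, 12 adjusted over the list alone, with a median of 0.35 and Ccne1 (0.83), Mcm3 (0.55) and Rrm1 (0.47) among them (camera adjusted p = 0.00015; adjusted p = 0.642 with an estimated correlation), while the G2/M list had a median of 0.11 and 0 calls over all genes or the list alone (camera adjusted p = 0.57). In the MAPK list, with a median of -0.14 and a mean of 0.12 (camera direction lower, adjusted p = 0.12), Fos rose and Etv1 fell by 1.31; 2 rose and 3 fell adjusted over the list alone. Dusp6 (0.13, adjusted p = 0.62), Spry4 (0.05, adjusted p = 0.87), Etv4 (-0.41, adjusted p = 0.27), Etv5 (-0.37, adjusted p = 0.13), Ccnd1 (-0.32, adjusted p = 0.26) and Mki67 (0.03, adjusted p = 0.91) did not pass. Hsp90aa1 (0.77), Hsph1 (0.61) and Hspd1 (0.56) rose among 10 heat shock genes, 4 of which rose adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.515 with an estimated correlation).

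The 8 largest rises at day 18 were Cfd (7.80), Car3 (6.18), Hp (6.02), Retn (5.89), Adipoq (5.70), Cidec (5.60), the major urinary protein gene Mup18 (5.56) and Wfdc21 (5.56); Mup18 has near-identical paralogs, so its level is uncertain. The falls were led by granzymes of a cluster on chromosome 14: Gzmf (-6.51), Gzmd (-5.97) and Gzme (-4.86) fell, and Gzmg, at 110 ± 27 (SD, n = 4) in the controls, was listed at 0 in both tumours. Gzmf lies at chromosome 14 from 56205263 to 56211417 (GRCm38) and fell from 104 ± 32 (SD, n = 4) to 0.11 ± 0.065 (SD, n = 2). These 4 genes are near-identical, so how reads were divided among them is uncertain. The list of cytotoxic lymphocytes and NK cells did not fall with them: its mean lay 1.125 and 0.036 log2 units over the controls in tumours 1 and 2. Nrn1 (-3.49), the mitochondrial tRNA mt-Tn (-3.23), the mast cell protease gene Mcpt1 (-2.81) and Lama5 (-2.61) followed. Egfr (0.99, adjusted p = 0.057), Pdgfrb (-0.49, adjusted p = 0.083), C1qa (1.32, adjusted p = 0.12), Cd8a (1.34, adjusted p = 0.17), Cd274 (0.47, adjusted p = 0.54), Mitf (-0.32, adjusted p = 0.45) and Axl (0.03, adjusted p = 0.86) were not called. The count was 370 genes without treated tumour 1, 418 without treated tumour 2, 541 without control day 3 tumour 2, 2220 and 695 without control day 6 tumours 1 and 2, 761 against the day 6 controls alone and 178 in a fit on the compared groups alone. The share of calls that were higher was 44.9% after quantile normalisation.

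**Figure D2:**
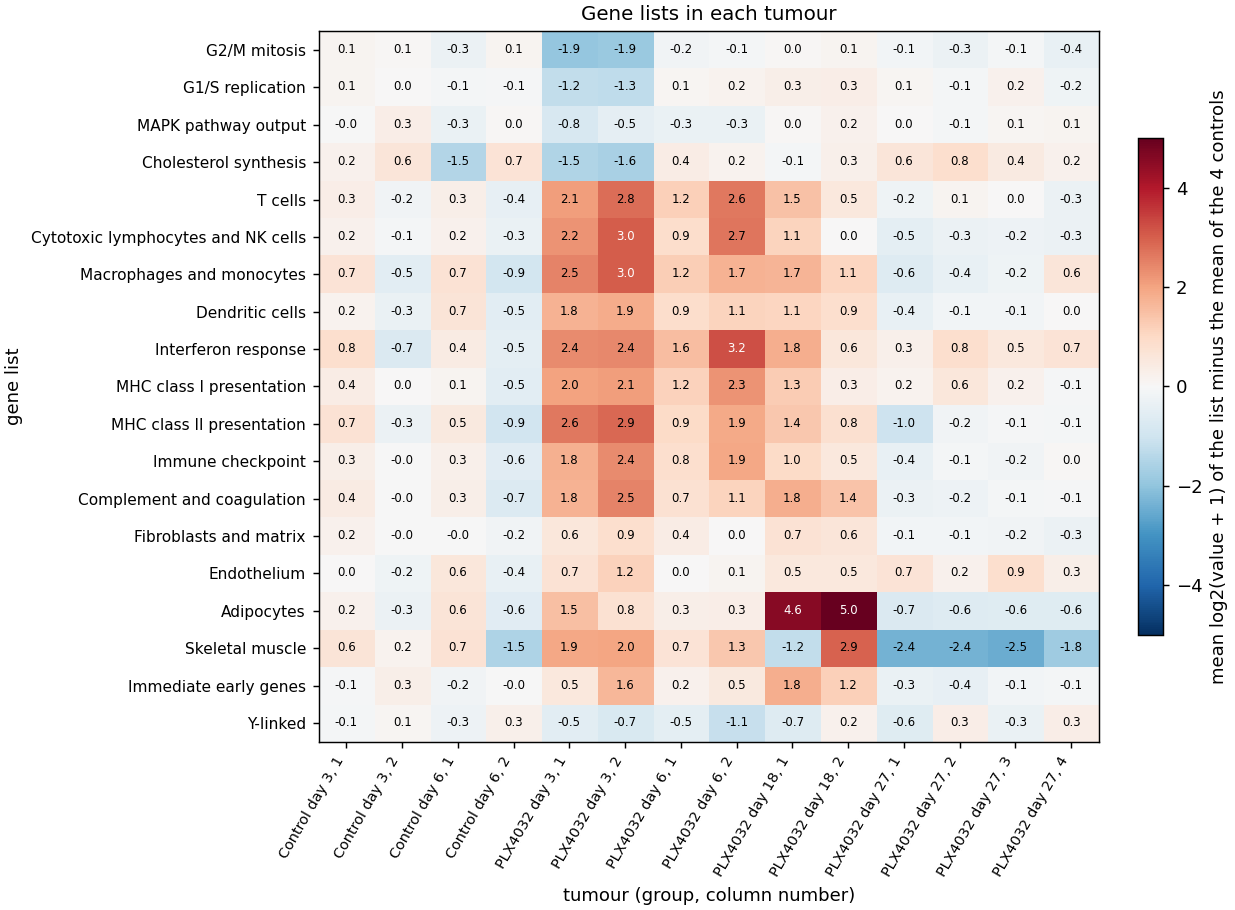
Mean log2(value + 1) of the genes of 19 lists (rows) in each of the 14 tumours (columns, numbered within a group), minus the mean of the 4 controls; red is higher, blue is lower, and each cell prints its value in log2 units. Adipocyte genes stand 4.56 and 5.00 over the controls at day 18, skeletal muscle genes 2.93 over them in tumour 2 of that day, and T cell genes 2.10 and 2.81 over them at day 3.

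At day 27 the T cell, macrophage and MAPK lists were not called, while chromosomes 6 and 19 and single genes stood apart. Hotairm1, a long noncoding RNA of the Hoxa cluster at chromosome 6 from 52156902 to 52162119 (GRCm38), went from 2.25 ± 1.5 (SD, n = 4) to 23 ± 3.5 (SD, n = 4), a log2 change of 3.01 (SE 0.32, adjusted p = 0.0015). Gzmf fell to 1.38 ± 0.66 (SD, n = 4), a log2 change of -5.46 (SE 0.37, adjusted p = 0.00013). In all, 1056 genes changed, 567 higher and 489 lower. Mki67 (-0.02, adjusted p = 0.93), Ccnd1 (0.03, adjusted p = 0.94), Etv4 (0.17, adjusted p = 0.67), Etv5 (0.18, adjusted p = 0.44), Spry4 (0.13, adjusted p = 0.68) and Dusp6 (0.33, adjusted p = 0.17) were not called.

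Many of the rises lay on chromosome 6. Among protein-coding genes of the autosomes with a mean of 5 or more, 183 of the 506 on chromosome 6 rose and 9 fell, and the median change of the chromosome was 0.35 against -0.19 to 0.06 on the other 18 autosomes. This count was made after the values had been seen. Met, the hepatocyte growth factor receptor gene at chromosome 6 from 17463800 to 17573980, rose from 21.3 ± 4.1 (SD, n = 4) to 43.5 ± 3.3 (SD, n = 4), a log2 change of 1.01 (SE 0.11, adjusted p = 0.0014). Braf, the gene of the drug's target at chromosome 6 from 39603237 to 39725463, rose from 5.60 ± 0.33 (SD, n = 4) to 7.85 ± 0.94 (SD, n = 4), a log2 change of 0.42 (SE 0.11, adjusted p = 0.044). Braf was chosen after its values were seen. On chromosome 19, 59 of 373 genes fell and 3 rose.

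**Figure D3:**
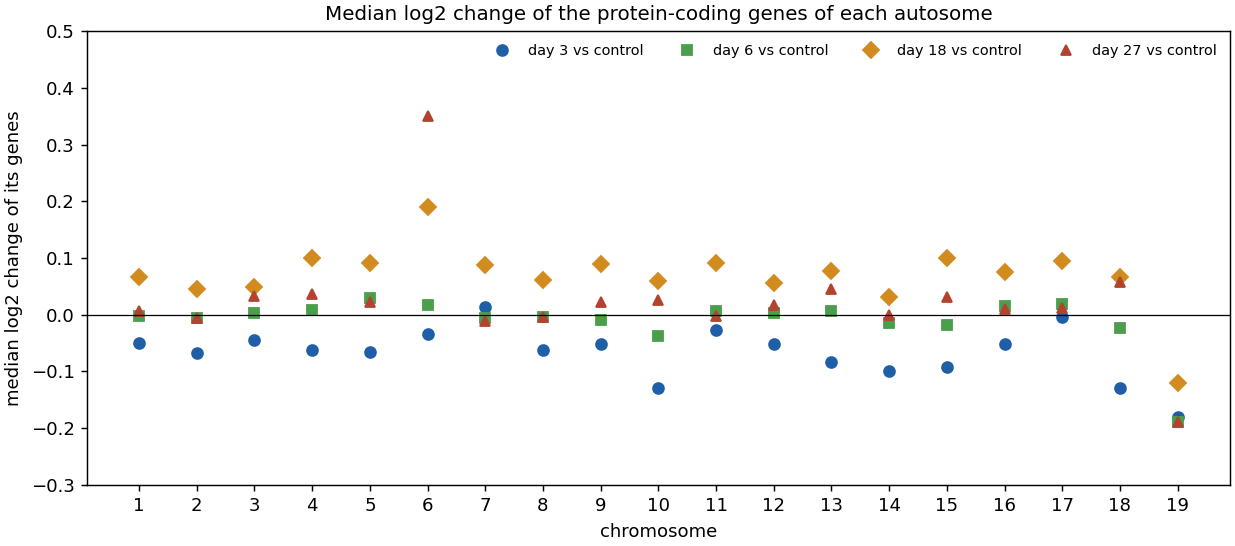
Median log2 change from the controls (y axis) of the protein-coding genes with a mean value of 5 or more on each autosome (x axis), for the 4 treated days, each shown by its own symbol and colour. Chromosome 6 stands at 0.35 at day 27 and 0.19 at day 18, and chromosome 19 lies between -0.19 and -0.12 at all 4 days.

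Of 18 endothelial genes 2 rose at day 27, Cdh5 (0.96) and Cldn5 (0.97), 3 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.0008; adjusted p = 0.888 with an estimated correlation). Of 10 genes of pericytes and smooth muscle 4 rose, namely Mcam (1.28), Kcnj8 (1.39), Higd1b (1.79) and Abcc9 (1.19), and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.07). Kcnj8 and Abcc9 lie on chromosome 6. Skeletal muscle genes were lower, with 3 of 18 called, Myl1 (-3.50), Tnnc2 (-3.75) and Acta1 (-4.37), 14 adjusted over the list alone, and a median of -2.30 (camera adjusted p = 7.7e-08; adjusted p = 0.888 with an estimated correlation). The list mean was 1.79 to 2.47 log2 units under the controls in the 4 tumours. Adipocyte genes had a median of -0.42 with 0 of 13 called over all genes or the list alone (camera adjusted p = 0.002), and fibroblast and matrix genes a median of -0.36 with 4 lower and 1 higher, 6 and 2 adjusted over the list alone; Lum (-1.24), Dcn (-1.04) and Fn1 (-0.63) fell and Tagln rose (camera adjusted p = 0.0056). G2/M genes had a median of -0.23 with 2 lower, Ccnb2 (-0.46) and Kif11 (-0.43), 3 adjusted over the list alone (camera adjusted p = 2.9e-05). Cholesterol synthesis genes (median 0.56, camera adjusted p = 0.0049) and interferon response genes (median 0.64, camera adjusted p = 0.019) had 0 members called over all genes or the list alone. The cholesterol list mean was 0.21 to 0.82 in the 4 tumours, against -1.48 in control day 6 tumour 1 and 0.23 to 0.67 in the other 3 controls, so this difference lay largely in that control. With an estimated correlation these 5 calls were lost too (adjusted p = 0.888 with an estimated correlation). Of the 7 lists that camera called at day 27, fry called 0. Of 20 T cell genes, 22 macrophage genes and 21 MAPK genes 0 were called over all genes or the list alone, with medians of -0.11, -0.12 and 0.10 (camera adjusted p = 0.62, 0.51 and 0.64).

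The 8 largest rises were Hotairm1, the apelin gene Apln (2.30), Tagln (2.30), Ccl11 (2.29), Col15a1 (2.25), Platr16 (2.23), Sh3gl3 (2.17) and Camk1g (2.11). Apln, the ligand of a vascular receptor, went from 11.4 ± 1.5 (SD, n = 4) to 61.4 ± 16 (SD, n = 4). The 8 largest falls were Gzmg (-6.37), Gzmf (-5.46), Gzmd (-5.09), Acta1 (-4.37, adjusted p = 0.041), Gzme (-4.32) and the mast cell protease genes Mcpt4 (-4.27), Tpsb2 (-4.05) and Cma1 (-4.00). Egfr, the epidermal growth factor receptor gene, rose from 6.15 ± 3.5 (SD, n = 4) to 11.3 ± 1.6 (SD, n = 4), a log2 change of 0.90 (adjusted p = 0.045). Axl (-0.25, adjusted p = 0.082), Mitf (-0.60, adjusted p = 0.14), Pdgfrb (-0.35, adjusted p = 0.15), Cd8a (0.40, adjusted p = 0.71), Cd274 (-0.22, adjusted p = 0.81), C1qa (0.27, adjusted p = 0.77) and Col1a1 (-0.23, adjusted p = 0.55) were not called. Because the mice behind the 4 tumours are unknown, each of the 3 ways to pair them was tried: averaging per mouse called 232, 162 or 250 genes, and a mouse effect in the model called 881, 475 or 992, for tumour 1 paired with 2, 3 or 4. The consensus correlations of these pairings were 0.103, 0.429 and 0.027, so the lowest counts came with the highest correlation. The count was 497 without control day 3 tumour 2, 511, 606 and 671 without treated tumours 1, 2 and 4, and 231 against the day 6 controls alone.

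Late tumours (days 18 and 27) were then set against early ones (days 3 and 6), which asks how tumours under continued treatment differed from those at its start. Cell division and MAPK output genes rose and immune genes fell. Etv4 rose by 1.59 (SE 0.18, adjusted p = 0.00023), Ccnd1 by 0.99 (SE 0.14, adjusted p = 0.00058) and Mki67 by 0.97 (SE 0.095, adjusted p = 0.00014), while Cd274 fell by 2.46 (SE 0.36, adjusted p = 0.00073) and Cd8a by 1.91 (SE 0.46, adjusted p = 0.008). In all, 6331 genes changed, 3260 higher and 3071 lower, and the higher share of 51.5% was 43.9% after median-of-ratios rescaling and 61.1% after quantile normalisation. The 4 day 27 tumours come from 2 mice, so these p-values are too small as well. Of the 3 Y-linked genes Ddx3y (0.65, adjusted p = 0.047) rose, 2 adjusted over the list alone, with a median of 0.65.

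All 24 G2/M genes (median 0.98) and all 24 G1/S genes (median 0.75) rose, the same numbers adjusted over the list alone, with Aurka (1.12), Cdc20 (1.20), Ccnb1 (1.18), Mcm2 (1.12) and Cdc45 (0.88) among them (camera adjusted p = 2.5e-16 and 4.6e-13; adjusted p = 0.414 with an estimated correlation for both). The early tumours were not alike in these genes. The G2/M list mean was 1.92 and 1.87 log2 units under the controls at day 3 but -0.17 and -0.10 at day 6, against 0.05 and 0.15 at day 18 and -0.36 to -0.09 at day 27. Of 21 MAPK genes 13 rose, 15 adjusted over the list alone, including Spry4 (0.67), Fosl1 (1.02), Etv5 (0.51) and Dusp6 (0.47) (camera adjusted p = 0.00023; adjusted p = 0.414 with an estimated correlation). Of 20 cholesterol synthesis genes 10 rose, 15 adjusted over the list alone, among them Dhcr7 (0.65) and Fdft1 (1.14) (camera adjusted p = 0.00034; adjusted p = 0.554 with an estimated correlation). That list mean was 0.39 and 0.18 at day 6, against -1.5 and -1.61 at day 3 and -0.11 to 0.82 in the late tumours.

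Of 20 T cell genes 19 fell (19 adjusted over the list alone, median -1.83), with Lck (-2.16), Cd28 (-1.67) and Zap70 (-2.10), and of 17 cytotoxic and NK cell genes 16 fell (17 adjusted over the list alone, median -2.07), with Gzma (-4.20), Klrd1 (-2.46) and the perforin gene Prf1 (-2.70). Of 22 macrophage genes 19 fell, also 19 adjusted over the list alone (median -1.47), with Cd68 (-1.74) and Lyz2 (-2.33), whose close copy Lyz1 can share its reads. All 16 class I and all 12 class II genes fell, the same adjusted over the list alone, with Tapbp (-1.35), Tap1 (-1.69), Ciita (-1.95) and H2-Ab1 (-2.04). Of 24 interferon genes 14 fell, 23 adjusted over the list alone, with Gbp2 (-2.84), Cxcl9 (-3.67) and Irf1 (-1.52), and of 16 checkpoint genes 13 fell, 15 adjusted over the list alone, with Pdcd1lg2 (-2.35), Ctla4 (-1.90) and Havcr2 (-1.80). The camera adjusted p of these 7 lists lay between 6.9e-09 and 5.7e-06; with an estimated correlation they were not called (adjusted p = 0.414 with an estimated correlation, 0.526 for the macrophage and interferon lists). In all 7 lists the mean of every day 27 tumour lay under that of every early tumour, while day 18 tumour 1 lay over day 6 tumour 1. The T cell list mean was 2.10 and 2.81 at day 3, 1.21 and 2.64 at day 6, 1.46 and 0.55 at day 18 and -0.29 to 0.13 at day 27, so the fall lay largely at day 27. Adipocyte genes rose in 9 of 13 cases, also 9 adjusted over the list alone, and skeletal muscle genes fell in 13 of 18, 15 adjusted over the list alone (camera adjusted p = 5.7e-05 for both; adjusted p = 0.414 and adjusted p = 0.554 with an estimated correlation). The adipocyte list mean was 4.56 and 5.00 at day 18 but -0.73 to -0.61 in the 4 tumours of day 27, under the 0.28 to 1.51 of the early tumours, so the rise lay at day 18. The muscle list mean was 2.93 in day 18 tumour 2, over the early tumours, and -2.47 to -1.24 in the other 5 late tumours.

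The 8 largest rises from early to late were Atg9b (3.43), Nptx1 (3.02), the neurofilament gene Nefl (2.61), the stromelysin gene Mmp10 (2.59), Dmp1 (2.11), Prtn3 (2.10), the kinesin gene Kif17 (2.06) and the endothelial gene Esm1 (1.96). Atg9b stood at 1.14 ± 0.62 (SD, n = 2) on day 3, 8.35 ± 2.2 (SD, n = 2) on day 6, 39.1 ± 11 (SD, n = 2) on day 18 and 57.4 ± 13 (SD, n = 4) on day 27, against 18.5 ± 4.5 (SD, n = 4) in the controls. The 8 largest falls were Gzmg (-6.65), Gzmf (-6.33), Gzmd (-5.96), AY036118 (-5.72, adjusted p = 0.015), Gzme (-4.98), Ly6i (-4.52), Gzma (-4.20) and Marco (-3.81). AY036118 varied by library, at 688 ± 860 (SD, n = 4) in the controls. C1qa fell by 1.25 and Mitf by 0.86, while Axl (0.07, adjusted p = 0.46), Egfr (0.20, adjusted p = 0.48), Pdgfrb (0.11, adjusted p = 0.53) and Col1a1 (-0.20, adjusted p = 0.41) were not called. With day 18 alone as late the count was 3220.

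The controls of day 6 and day 3 were compared to see whether they can serve together. With limma 0 genes passed an adjusted p of 0.05, and 886 had an unadjusted p under 0.05 where 792 would by chance. With the preset correlation camera called 12 lists, of which 0 were called with an estimated correlation and 0 by fry. Cholesterol synthesis genes had a median of -0.72 and genes of the unfolded protein response a median of -0.38, with 0 members called over all genes or the list alone (camera adjusted p = 1.6e-07 and 1.2e-07; adjusted p = 0.71 and adjusted p = 0.567 with an estimated correlation). The cholesterol list mean was -1.48 in control day 6 tumour 1 but 0.67 in tumour 2 of that day, over the 0.23 and 0.59 of the day 3 controls, so that fall lay in 1 tumour. Leaving out control day 6 tumour 1 or 2 gave 7 and 31 genes.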

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

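The tests of the Y-linked, G2/M, MAPK and macrophage lists given here, and the divisions that keep mice together, were chosen after the results were seen; the other counts of splits were not. Differences between treated days were tested directly, with the controls cancelling. Between day 6 and day 3, 2892 genes differed, 1730 higher and 1162 lower at day 6. Between day 18 and day 6, 239 differed, and between day 27 and day 18, 1592. Between day 27 and day 3, 8234 differed, and between late and early tumours, 6331. The 10 treated tumours can be divided into 6 and 4 in 210 ways, of which 100 were drawn: 1 split, the real one, called as many as the 4021 genes found with late and early tumours as 1 group each in a fit of all tumours, and the highest other split drawn called 1. Of the 46 divisions that keep the 2 tumours of a mouse together, under each of the 3 pairings, the real one also called the most, but the division of day 27 from all other treated tumours called 3607, so much of this contrast lies between day 27 and the rest. Of the 35 divisions of the 4 day 27 tumours and 4 controls, 1, again the real one, gave as many as the 1061 genes found with the 4 controls as 1 group in a fit of all tumours, with 1 gene in the highest other. With mice kept together, a share of 0.022 of the late against early divisions called as many genes. That argues against chance division but does not exclude it. The 2 day 18 tumours are taken as separate mice there, which the labels do not show. For day 27 most of the 35 divisions take tumours of 1 mouse apart; only 7 keep them together, too few for a share under 0.05, with 1061 genes in the real one and 1 in the highest other.

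Tumours far from the rest of their group of 4 were found in 15 of 148 gene and group combinations, where chance gives about 1 in 20, or 7. Each gap is given as a share of the group's range. At day 27, tumour 2 stood apart for Marco (0.899, at 0.653 against 0.0524 to 0.113), Lyz1 (0.917, at 1.63 against 0.178 to 0.298), Il11 (0.882, at 20.9 against 8.91 to 10.3) and Spry4 (0.873, at 31.2 against 48.7 to 51.3). Tumour 4 of that day stood apart for Cd8a (0.868, at 1.10 against 3.16 to 3.48), Cfd (0.895), Ccl11 (0.860, at 90.8 against 36.6 to 44.2) and Platr16 (0.883). It also did so for the muscle actin gene Acta1 (0.949, at 7.29 against 0.754 to 1.09) and the mast cell gene Cma1 (0.8295, at 7.80 against 0.54 to 1.78). Cidec and Mup18 were flagged at 0.0297 and 0.12 in tumour 4, with the other 3 tumours listed at 0. There the share is 1.0 for any value above 0, so it says nothing about that tumour. Marco, Cidec and Mup18 lay under 1, the level used for testing, in all 4 tumours of day 27. Among the controls, day 6 tumour 2 stood apart for Saa3 (0.834, at 3.29 against 74.1 to 88.2), day 6 tumour 1 for Tpsb2 (0.846, at 274 against 38.8 to 74.9) and day 3 tumour 2 for Mmp10 (0.832, at 28.6 against 2.60 to 6.96).

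At day 3 dividing-cell genes fell and immune genes rose, while the 3 Y-linked genes had a mean change of -0.64 ± 0.37 (SE). Of these only Ddx3y was called over all genes and 0 over the list alone. Ddx3y stood at 7.87 to 25.1 in the 14 tumours, and the female hosts lack it, so it came from the grafted cells. Xist stood at 51.3 and 78.5 in the treated tumours of day 3 against 7.98 to 24.7 in the controls. A smaller share of grafted cells is therefore a candidate explanation. The Y-linked genes are an uncertain gauge of that share. At day 27 Ddx3y stood at 12.15 in tumour 1 and 22.99 in tumour 2, while Ptprc stood at 14.14 and 14.49. If the Y-linked genes do track it, a smaller share alone is argued against for the G2/M list. The mean of that list fell by 1.25 ± 0.40 (SE) log2 units more than that of the Y-linked genes. For the macrophage list a smaller share alone is argued against without the Y-linked genes. Its mean change exceeded that of the endothelial list by 1.82 ± 0.50 (SE), where fewer grafted cells would raise both alike. For the MAPK list a smaller share stays open, since its mean change differed from that of the Y-linked genes by 0.02 ± 0.36 (SE). A response of the cells to the drug, which the design names, is open for all of these and was not tested apart from the share of cells. Late against early, where the Y-linked genes had a median of 0.65, no test of the share of grafted cells was run. The macrophage list mean was 1.24 to 3.04 in early tumours and -0.645 to 0.603 at day 27. That of endothelium was 0.023 to 1.17 and 0.209 to 0.855, and that of fibroblasts and matrix 0.039 to 0.852 and -0.287 to -0.149. More grafted cells would lower these lists alike. The macrophage and fibroblast lists fell without overlap between these tumours, while the ranges of the endothelial list overlapped. No standard error of these differences was computed, so a larger share of grafted cells stays open for the macrophage fall at day 27. For the other genes it stays open as well.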

How the results depend on the processing

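The pairings of day 27 tumours and the choice of 1 late day were made after seeing the data. Settings of pseudocount, filter, median-of-ratios and quantile scaling, variance trend and sample weights left all 6 counts within 1.5 times. Fitting the compared groups alone gave 0 genes at day 6 and 178 at day 18, with fewer samples behind the spread. Same-day controls gave 8 at day 6, and day 6 controls gave 761 at day 18 and 231 at day 27. At day 27 averaging per mouse gave 232, 162 and 250 for the pairings of tumour 1 with 2, 3 and 4, and a mouse effect for the pairing with 3 gave 475. Late against early gave 3220 with day 18 alone. The cause of these shifts was not tested. Leaving out a tumour gave 4345 to 7365 genes at day 3, 0 to 2145 at day 6, 370 to 2220 at day 18, 497 to 1140 at day 27, 4657 to 6299 late against early and 0 to 31 between the controls. For named genes 96 of 1080 such values lost their call and 10 gained one; 1 of 150 was lost and 1 gained both under a pseudocount of 0.1 and under median-of-ratios rescaling, and no called direction turned. Of 198 list results, the estimated correlation ended 92 calls, fry ended 40 and added 9, and rescaling ended 2 and added 1. No paired analysis was possible because the groups compared share fewer than 2 animal numbers in the labels and the columns carry none. Without read counts, what depth limits cannot be stated.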

Other observations

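The list of receptor tyrosine kinases and their ligands was not called by camera on any treated day or late against early (adjusted p = 0.13 to 0.874), but fry called it at day 18 (adjusted p = 0.0469) and late against early (adjusted p = 0.00542). Of 26 tested, 7 rose and 9 fell at day 3, 8 and 9 adjusted over the list alone (camera direction lower, adjusted p = 0.469), with a median of -0.22 and a mean of 0.01. Met fell by 1.02 at day 3, then stood 0.73 over the controls at day 18 and 1.01 over them at day 27. Igf1, the growth factor gene, rose by 2.63 at day 3 and 2.40 at day 18, and Gas6, a ligand of Axl, rose by 3.35 at day 18, from 17.9 ± 13 (SD, n = 4) to 166 ± 78 (SD, n = 2). Other cells may have brought these rises, which was not tested: the macrophage list mean was 2.49 and 3.04 in the tumours of day 3, and at day 18 that of adipocytes was 4.56 and 5.00. Pdgfb rose by 1.3 at day 3 and 1.25 at day 27. Sox10, at 0.0756 in the controls, averaged 1.46 ± 0.69 (SD, n = 4) at day 27, a log2 change of 1.15 (adjusted p = 0.033).

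Mir6236 took 0.489% to 5.87% of a column's total, with the highest share in control day 6 tumour 1 and 2.95% in control day 3 tumour 2. The first principal component, with 52.8% of the variance, placed the controls between -55.2 and -3.65 and the day 3 tumours at 74.7 and 94.3.

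The patterns by chromosome were noticed first, and the tests of correction and percentiles were set before their results were seen. All 19 autosomes were compared. Chromosome 6 minus the other autosomes stood at -0.01 to 0.00 in the 4 controls, 0.01 to 0.03 in the 4 tumours of days 3 and 6, 0.08 and 0.15 at day 18, and 0.29 to 0.37 at day 27 (exact permutation p = 0.029 for day 27 against control, 2-sided, the smallest 70 assignments can give; adjusted over 19 autosomes 0.11). All 14 windows of 10 Mb with at least 10 genes had a positive median at day 27, from 0.26 to 0.48, and none of 10000 random gene lists matched on expression exceeded 0.06. GC content and transcript length are argued against, since the median after removal of their trend was 0.32, with 0.03 the highest elsewhere. A change in the immune and stromal cells that differed at day 3 is argued against. Genes that changed little at day 3 had a median of 0.36, with 0.07 the highest elsewhere. Cells that differed only at day 27 are not covered by that choice of genes. A hypothesis is that the grafted cells of day 27 may carry extra copies of chromosome 6, where Braf lies: the 25th percentile was shifted by 0.29 and the median by 0.34, as when most genes move together, but RNA alone does not show copy number, and the 4 tumours came from 2 mice.

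Chromosome 19 minus the other autosomes stood at 0.05 and 0.05 in the day 3 controls, -0.07 and -0.03 in the day 6 controls and at -0.25 to -0.12 in the 10 treated tumours (exact permutation p = 0.001, 2-sided, the smallest 1001 assignments can give; adjusted over 19 autosomes 0.019). These assignments treat all tumours as separate, but the 4 of day 27 came from 2 mice, so both p-values are too small. Whether the adjusted one would stay under 0.05 with mice kept together was not tested. The mean over the 4 treated days had a negative median in all 6 windows, from -0.22 to -0.07. The median of this mean was -0.17 after removal of the trend on GC content and length. Among genes that changed little at day 3, the median of the mean over days 6, 18 and 27 was -0.20. The lowest of the other autosomes were at 0.00 and -0.01 in these 2 tests. This argues against GC content and length, and against the immune and stromal cells that differed at day 3. Cells that differed only on later days are not covered. A hypothesis is fewer copies of chromosome 19 in the treated cells, or more in the control cells. The 75th percentile moved by -0.15 with the median's -0.19, as when most genes move together. Any shift shared by most genes of the chromosome would give this, and RNA alone does not show copy number. At day 3 the chromosome hardly stood apart: its median was -0.18 against -0.13 for the lowest other autosome, with 37.5% of its genes above 0 against 37.8% there. Whether cells with it were present before treatment cannot be read from these groups.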
